A study of Homo sapiens with 4 samples.

How the data were processed

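RNA levels were measured in human breast cancer cells on Clariom S Human arrays, a short-oligonucleotide platform that reports 1 value per transcript cluster. Per the labels' protocols, each of the 4 conditions was 1 array hybridised with RNA combined from 3 cultures, and the RNA integrity number of the RNAs was above 9. The deposited values were log2 expression values, which the submitters' processing notes credit to RMA (robust multi-array averaging, a background correction, quantile normalisation and probe summarisation method) with no version. The settings of that step and the genome build of the array's design are not given in the sources used here, so no coordinates are reported. The deposited table held 21448 transcript clusters on 4 arrays with no missing value, and its values ran from 1.62 to 17.86. Medians of all transcript clusters were 5.65, 5.66, 5.54 and 5.60 in MCF-7 siNeg, MCF-7 siTRIM47, OHTR siNeg and OHTR siTRIM47, so the deposited arrays lay on 1 scale.

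Transcript clusters were named from the platform annotation supplied with the table: 17709 had 1 gene symbol, 0 had several and 3739 had no listed gene. The 17709 named clusters covered 17687 genes, and for the 20 genes with more than 1 cluster the cluster with the highest mean was used. A gene passed the expression filter when the highest of its 4 values reached the median of all gene values, 6.11 on the log2 scale, which left 9399 genes. No detection call was used, so a fold change whose lower side lies near the low end of the arrays is set in part by background there.

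With 1 array per condition, the 4 comparisons between single arrays (siTRIM47 against siNeg in each line, and OHTR against MCF-7 under each siRNA) were given as log2 differences with no replicate check and no p-value, and genes were counted at 2-fold. As a yardstick of error, the robust SD over genes of the difference between the responses of the 2 lines was divided by the square root of 2, which gave 0.36 on the log2 scale (1.29-fold); it mixes array noise with real differences between the lines and is no replicate error. Effects common to both pairs of arrays were tested in an additive model of line and siRNA, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and Benjamini-Hochberg adjustment over the 9399 genes. That fit leaves 1 residual degree of freedom per gene, moderated by 9.56 prior degrees of freedom shared across genes, and its residual holds any difference between the responses of the 2 lines together with array noise. The words rose and fell are used of genes that passed adjusted p = 0.05 in that fit. The p-values cover the spread between pooled arrays, not between cultures.

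The limma step was tested on simulated data, 20 sets of 9399 genes with 200 changed genes and the real fit's variance prior. Each changed gene was given the same change in both lines, so the shares below do not cover genes whose responses differ between the lines. For the siTRIM47 effect over both lines, 34.2% of 2-fold and 98.8% of 4-fold changes were recovered, and 9.9% of calls were false against the 5% aimed for. The false share ran from 0.8% to 19.4% between sets. Adjusted p-values near 0.05 are therefore less strict than their value.

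A total of 22 gene lists was fixed before the data were examined: NF-kB targets, components of the PKC, PKD and NF-kB pathway, estrogen-induced genes, luminal genes, basal and mesenchymal genes, growth factor receptors and adaptors, G1/S and DNA replication genes, G2/M genes, interferon-stimulated genes, p53 targets, cholesterol genes, fatty acid synthesis genes, unfolded protein and ATF4 response genes, hypoxia and glycolysis genes, AHR and NRF2 targets, drug transporters, BCL2 family genes, immediate early and AP-1 genes, other TRIM genes, immune cell markers, fibroblast and endothelial markers, and reference genes. A list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays, for the 20 lists with at least 5 members past the filter. Members were also counted at 1.5-fold, and additive calls were adjusted over all genes and over the list alone. On simulated lists of 29 genes in the OHTR comparison, 4% of unshifted lists and 97% of lists shifted by 0.5 on the log2 scale fell outside the central 95%.

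The genes named followed a rule fixed beforehand: TRIM47 and ESR1 throughout, the 10 highest and 10 lowest differences past the filter in each comparison and the 10 highest and 10 lowest additive calls, the 5 highest and 5 lowest differences between the responses, and up to 4 members per list with the largest differences, with PRKCE and PRKD3. List members called in the additive fits are named beside their list's count. The alternatives tried were no filter, a filter at the 75th percentile, a 1.5-fold threshold, cyclic loess, centring on array medians, the mean of a gene's clusters, eBayes with an intensity trend or robust, an added 1.5-fold threshold on the additive calls, unmatched random lists, list means, and the correlation without the 1% largest responses. Swapped siRNA labels were added after the data were seen. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.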

Results

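Gene expression was profiled in MCF-7, an estrogen receptor-positive human breast cancer cell line, and in OHTR, a derivative of MCF-7 resistant to 4-hydroxytamoxifen (OHT, the active metabolite of tamoxifen) and kept in 1 µM OHT. Both lines received 10 nM of an siRNA against TRIM47 (siTRIM47) or of a negative control siRNA (siNeg) by reverse transfection, and RNA was taken 48 h later. TRIM47 is a member of the tripartite motif family of RING-type ubiquitin ligases. RNA of 3 cultures per condition was combined on 1 array, giving 4 arrays in a 2 by 2 design with no replicate array, so the number of arrays limits the precision of each value. Differences between single arrays have no replicate check and no p-value. The OHTR siTRIM47 array is titled OHTR5 and the OHTR siNeg array OHTR, and whether both came from the same resistant cells is not stated.

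TRIM47 itself, the target of the siRNA, was lower with siTRIM47 in both lines. Its level was 3.34 with siNeg and 3.11 with siTRIM47 in MCF-7, a difference of -0.23 on the log2 scale (1.17-fold), and 4.03 and 3.01 in OHTR, a difference of -1.02 (2.03-fold). Among the 500 genes of the nearest mean level, 35.6% lay below the MCF-7 difference and 0.8% below the OHTR difference. Under siNeg, TRIM47 was 1.62-fold higher in OHTR than in MCF-7, and under siTRIM47 it differed by -0.10. TRIM47 ranked at percentiles of 15.9 to 35.2 among all genes on the 4 arrays, below the expression filter, so its values sit near the low end of the arrays and are a weak check of the siRNA labels.

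In MCF-7 cells, which asks what siTRIM47 alters in the parental line, the 29 G1/S and DNA replication genes were higher with siTRIM47 as a list (median 0.45). The replication licensing factor CDT1 was 4.06-fold higher, and the MCM helicase genes MCM2 and MCM5 were each 2.14-fold higher, while MCM3 of the same helicase was at -0.80. The highest single differences were those of TARP, a transcript of the T cell receptor gamma locus (3.13 on the log2 scale), NCR3LG1, the ligand of the natural killer cell receptor NKp30 (2.59), and TGFBI, a matrix protein induced by TGF-beta (2.52). The lowest were those of MLLT11 (-3.27), PHLDA1 (-2.62) and CYB5R3, a cytochrome b5 reductase (-2.59), followed by the Polycomb-associated gene PHF1 (-2.55), the apoptosis effector BAK1 (-2.44) and the integrin subunit gene ITGB1 (-2.41). CREB5, the cilium transport gene IFT46, the nuclear receptor gene HNF4G, POTEJ, MREG, PSG8 and the histone gene H2BC14 were from 2.47 to 2.11 higher. FAM217B, TMED5, MAPRE3 and CNN2 were between -2.22 and -2.44. Of 9399 genes, 297 were at least 2-fold higher and 265 at least 2-fold lower, an order that turned after cyclic loess (272 and 288) and after centring (237 and 311).

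Of the gene lists in MCF-7, 3 had a median above the central 95% of random lists. The 29 G1/S and DNA replication genes had a median of 0.45 (interquartile range of members 0.08 to 0.79, percentile 100), with 11 at least 1.5-fold higher and 2 lower; MCM10, which loads replication factors at origins, was 2.17-fold higher. The 11 immediate early and AP-1 genes had a median of 0.50 (percentile 99.3), led by JUN (1.89), while the ERK phosphatase gene DUSP5 was lower (-1.77). The 24 estrogen-induced genes had a median of 0.31 (percentile 99.7), with GREB1 at 1.28 and MYB at 1.19. The 27 G2/M genes lay just inside with a median of 0.20 (percentile 96.9), and HMMR, BIRC5 and BUB1 were 2.88-fold, 2.56-fold and 2.03-fold higher. NF-kB targets had a median of 0.18, PKC, PKD and NF-kB components 0.13, interferon-stimulated genes 0.14 and p53 targets 0.10, all inside. ESR1, which encodes estrogen receptor alpha, differed by 0.45. Receptors and adaptors had a median of 0.30 but a mean of -0.11, since TGFA (-1.93) and INSR (-1.03) were far lower. Without the expression filter the estrogen-induced list lay inside (percentile 96.7, 31 members), and with the filter at the 75th percentile the immediate early list had too few members to be placed. Of the lists inside, the G2/M list lay above with list means (percentile 99.96), and with the filter at the 75th percentile the NF-kB list lay above (0.39, percentile 97.8) and AHR and NRF2 targets below (-0.30, percentile 2.29); without the filter the NF-kB median turned to -0.11.

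In OHTR cells, where the question is what siTRIM47 alters in the resistant line, interferon-stimulated genes were higher with siTRIM47 (11 genes, median 0.86) and DNA replication genes were lower (29 genes, median -0.65). IFIT1, an interferon-induced antiviral protein, was 22.5-fold higher and OAS1, an interferon-induced sensor of double-stranded RNA, 7.03-fold higher. The stress cytokine gene GDF15 was 17.7-fold higher and the cell cycle inhibitor gene CDKN1A 2.96-fold higher. The carcinoembryonic antigen family genes CEACAM5 (3.80 on the log2 scale), PSG9 (3.66), PSG8 (3.25) and CEACAM1 (2.73) were also among the 10 highest, although these genes are close in sequence and their probes could share signal. FILIP1L, the importin gene KPNA7 and the ubiquitin ligase subunit gene FBXO32 were 2.97, 2.93 and 2.74 higher. The lowest were PRC1, which bundles microtubules in cytokinesis (-3.72), ACSL1, an acyl-CoA synthetase (-3.65), BAK1 (-3.59), the cargo receptor gene TMED5 (-3.18) and MAGT1, which acts in protein glycosylation and magnesium uptake (-3.15). GAS2L1, KIAA0319, ISOC1, FAM217B and CYB5R3 ranged from -3.14 to -2.80. Of 9399 genes, 604 were at least 2-fold higher and 585 at least 2-fold lower (573 and 596 after centring).

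The G1/S and DNA replication list in OHTR had a median of -0.65 (interquartile range -0.87 to -0.24, percentile 0), with 15 of 29 members at least 1.5-fold lower and 1 higher. MCM3, lower in both lines, was at -2.12, MCM10 at -1.80 and the origin recognition gene ORC1 at -1.61, and the sliding clamp gene PCNA was 2.79-fold lower, while MCM5 was the other way at 0.71. G2/M genes had a median of -0.42 (percentile 0.02), with CDK1 and AURKA at -1.08 and -1.07 and HMMR the other way at 1.17. The 11 interferon-stimulated genes had a median of 0.86 (percentile 99.9), with 6 at least 1.5-fold higher and 0 lower, IRF9 at 1.97 and IFI6 at 1.74 among them. Hypoxia and glycolysis genes had a median of 0.56, with 10 of 20 at least 1.5-fold higher, KDM3A at 1.64 and BNIP3L at 1.34 but the oxygen sensor gene EGLN1 at -1.78. Immediate early and AP-1 genes (0.72), NF-kB targets (0.53, with PLAU at 1.34 and NFKB2 at 1.17) and BCL2 family genes (0.40) lay above, and the 7 drug transporters (-0.65, with ABCC2 at -1.39) below. Estrogen-induced genes (0.04), p53 targets (0.26), cholesterol genes (0.24), fatty acid synthesis genes (-0.05), unfolded protein genes (-0.10), AHR and NRF2 targets (0.07) and PKC, PKD and NF-kB components (0.05, with TRAF3 at -1.46) lay inside. PKC, PKD and NF-kB components, receptors and adaptors and basal genes had means of -0.04, 0.10 and 0.05, opposite in sign to their medians of 0.05, -0.02 and -0.15. The kinase genes PRKCE and PRKD3 differed by 0.06 and 0.03, and ESR1 by 0.94. Without the expression filter the NF-kB (percentile 90.3), immediate early (93.2) and drug transporter (2.59) lists lay inside, and the BCL2 list had a mean of 0.03 beside its median of 0.40 and lay inside unmatched random lists. With the filter at the 75th percentile the interferon, immediate early and drug transporter lists had too few members to be placed. Of the lists inside, p53 targets (percentile 99.5) and cholesterol genes (99.3) lay above with list means, and AHR and NRF2 targets below with the filter at the 75th percentile (-0.55, percentile 1.07).

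**Figure D1:**
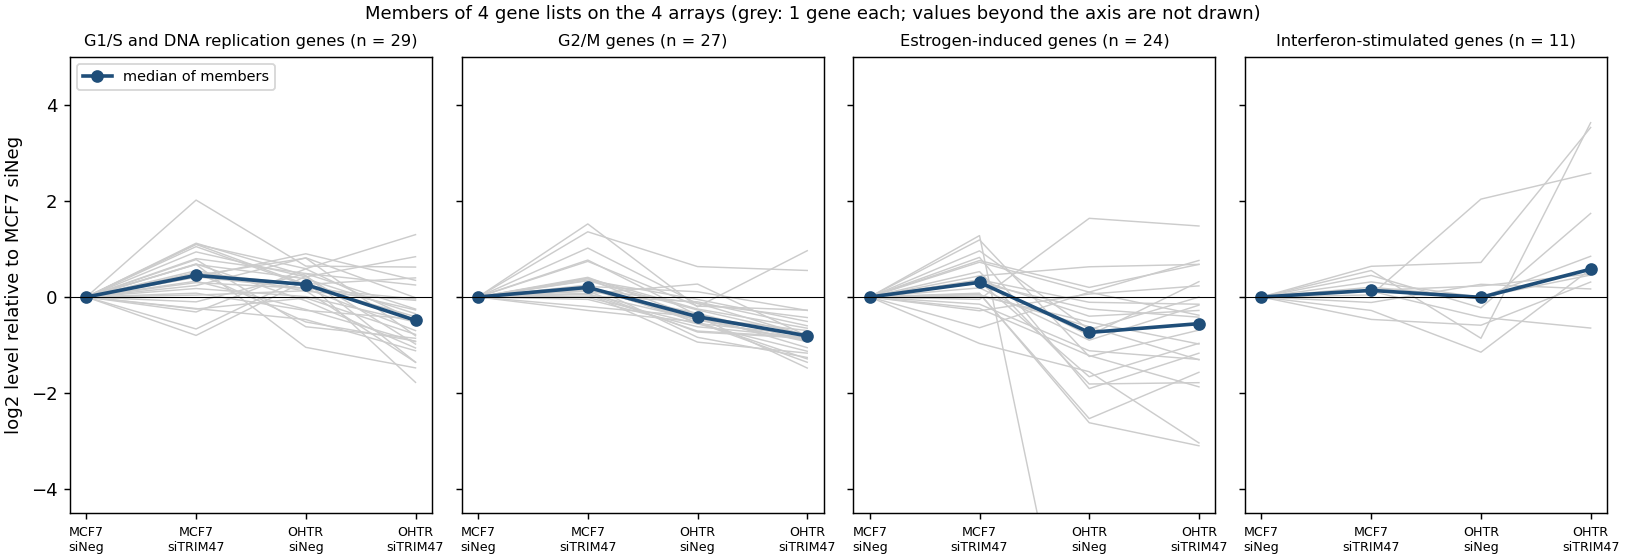
Each panel shows 1 gene list on the 4 arrays, as log2 level relative to the MCF-7 siNeg array, with a grey line per gene and the median of members in blue. The median of the G1/S and DNA replication genes lies above 0 with siTRIM47 in MCF-7 and below 0 with siTRIM47 in OHTR; GREB1 runs below the axis in OHTR.

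Across both lines, siTRIM47 raised GDF15, TGFBI and JUN and lowered BAK1, PRC1 and ITGB1. BAK1, which permeabilises mitochondria in apoptosis, fell by 3.01 on the log2 scale (SE 0.30, limma adjusted p = 0.0012), and its regulators BCL2L11 (BIM) and BAD rose by 1.41 and 0.91. BAD was at a limma adjusted p of 0.0499 and lost its call after centring on array medians and without the expression filter. GDF15 rose 7.32-fold (2.87, SE 0.46, adjusted p = 0.0073), TGFBI 6.12-fold (2.61, SE 0.24, adjusted p = 0.0012) and IFIT1 by 2.52 (SE 0.65, adjusted p = 0.047). Most of the IFIT1 change came from OHTR (4.49, against 0.55 in MCF-7), and only its OHTR siTRIM47 value reached the expression filter. The cytokinesis gene PRC1 fell by 2.57 and the integrin gene ITGB1 fell by 2.45. PSG8, CEACAM5, PSG9, IFT46, HNF4G, CREB5 and the ARF exchange factor gene CYTH3 rose by 2.68 to 2.23. TMED5, CYB5R3, FAM217B, MLLT11, MAGT1, ISOC1 and ACSL1 fell, with log2 changes from -2.76 to -2.41. Each of these values is the mean of the 2 pairs of arrays. The pairs were unequal for GDF15 (1.59 in MCF-7 and 4.15 in OHTR), PRC1 (-1.42 and -3.72), CEACAM5 (1.43 and 3.80) and ACSL1 (-1.17 and -3.65). They were close for TGFBI (2.52 and 2.71) and ITGB1 (-2.41 and -2.49).

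In limma's additive fit, 290 genes rose and 312 fell with siTRIM47 at an adjusted p under 0.05, and 2169 of 9399 had an unadjusted p under 0.05. The 602 called genes had the same sign in both pairs of arrays. This follows from the fit, where pairs of opposite sign give a small mean and a large residual. It is therefore no separate evidence of a shared response. Without the expression filter 215 of the 602 remained called, and of 44 named genes 22 lost their call, IFIT1, OAS1, ACSL1 and MCM3 among them; IFIT1 also lost it with robust eBayes, and ATF3 and EGLN3 with an intensity trend. Of the list members named below, TGFBI, HMMR, GDF15, EGLN1, BCL2L11, BAK1 and JUN kept their call without the filter and the others lost it. ESR1 differed by 0.70 (SE 0.25, adjusted p = 0.12) and passed the threshold only with an intensity trend in eBayes.

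By list, the immediate early and AP-1 genes JUN, KLF6, ATF3 and ZFP36 rose and DUSP5 fell, 5 of 11 members (1, JUN, without the expression filter), and 5 rose and 1 fell when adjusted over the list alone. Of 12 BCL2 family genes, 2 rose and 1 fell, the same counts adjusted over the list alone. Of 11 interferon-stimulated genes IFIT1 and OAS1 rose, and 3 adjusted over the list alone. OAS1 differed by 0.64 in MCF-7 and 2.81 in OHTR, and it too reached the filter only on the OHTR siTRIM47 array. The oxygen sensors EGLN1 and EGLN3 fell, with log2 changes of -1.88 and -0.92; adjusted over the list alone, 3 of 20 hypoxia genes rose and 2 fell. Of 29 G1/S genes MCM3 and UNG fell, and adjusted over the list alone 1 rose and 2 fell. Of 10 NF-kB targets limma called 0, with 3 at an unadjusted p under 0.05, and 3 rose when adjusted over the list alone. Of 15 PKC, PKD and NF-kB components the protein kinase D gene PRKD2 rose by 1.05 (SE 0.24), the same count adjusted over the list alone.

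Among p53 targets GDF15 rose and ZMAT3 fell, and among AHR and NRF2 targets CYP1A1 rose and PIR fell, with 2 rising and 3 falling when adjusted over the list alone. In the unfolded protein list ATF3 and DDIT4 rose, 2 of 22 by either adjustment. ELF3 rose among luminal genes, TGFBI among basal genes, HMMR among G2/M genes and the cholesterol gene MVD in its list; adjusted over the list alone the count stayed at 1 in the first 3 lists and was 0 for cholesterol genes. MYBL1 fell among estrogen-induced genes (list alone: 3 rose, 1 fell), FGFR4 among receptors (list alone: 1 rose, 1 fell), ACSL1 among fatty acid genes (list alone: 2 rose, 3 fell) and ABCG1 among drug transporters (list alone: 3 fell). Of the 20 other TRIM genes and of the 12 reference genes limma called 0 by either adjustment, with 2 at an unadjusted p under 0.05 in each. CD68, the only immune cell marker past the filter a lysosomal protein, rose 3.21-fold, and of the fibroblast markers ACTA2 was at -0.39 in MCF-7 and 1.30 in OHTR while COL1A2 was at -0.81 and -0.57. Of these 2 markers limma called 0 over all genes, with 1 at an unadjusted p under 0.05, which fell adjusted over the list alone.

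The responses of the 2 lines, which share no array, went together across genes, with a Pearson r of 0.55 and a Spearman rho of 0.49 over 9399 genes that are not independent replicates. PSG8, TGFBI, IFT46, BAK1, TMED5 and CYB5R3 were more than 4-fold apart in the same direction in each line. At 2-fold, 132 genes were higher in both lines against 19.1 expected for independent lists, and 154 were lower in both against 16.5. At 4-fold, 7 were higher and 7 lower in both, against 0.09 expected for each. The largest differences between the responses, OHTR minus MCF-7, were those of IFIT1 (3.94), CEACAM1 (2.99), KPNA7 (2.80), GDF15 (2.55) and the circadian repressor gene CIART (2.49), and at the other end MCM10 (-2.93), BCAT1, a branched-chain aminotransferase (-2.66), the E2F family gene E2F6 (-2.62), NCR3LG1 (-2.56) and ACSL1 (-2.48). In all, 808 genes differed at least 2-fold between the responses, 360 toward higher and 448 toward lower in OHTR. MCM10 and PRSS22, chosen after their values were seen, were the only genes at least 2-fold apart in opposite directions, MCM10 with 1.12 in MCF-7 and -1.80 in OHTR, and the serine protease gene PRSS22 with -1.14 and 1.03. With 1 array per condition none of these differences between the lines was tested.

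**Figure D2:**
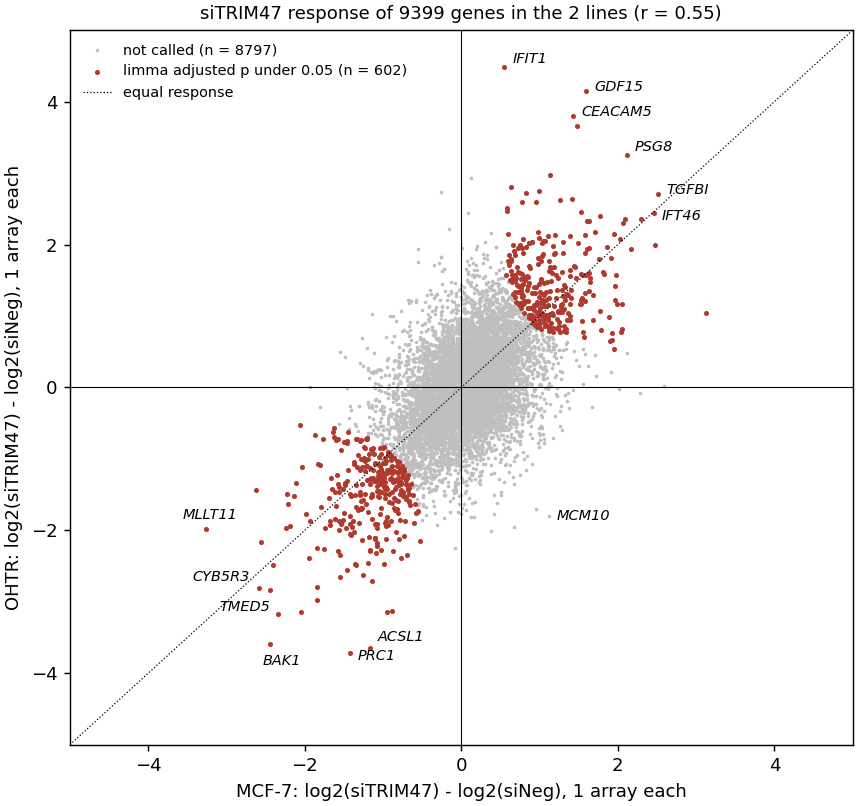
The log2 difference between siTRIM47 and siNeg in MCF-7 (x axis) is plotted against that in OHTR (y axis) for 9399 genes, with the 602 genes called by limma's additive fit in red and the dotted line marking equal responses. Points spread along the dotted line (r = 0.55), and IFIT1 and GDF15 lie above it.

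OHTR and MCF-7 under siNeg, the comparison of the resistant with the parental line, differed most in GREB1 and 3 genes of the cadherin superfamily, all lower in OHTR. GREB1, an estrogen-induced coregulator of the estrogen receptor, was at 3.14 in OHTR and 12.86 in MCF-7, a difference of -9.72 on the log2 scale. The protocadherin genes PCDH10 (-9.42) and PCDH7 (-9.20), the cadherin gene CDH12 (-7.77), the AMPA receptor subunit gene GRIA2 (-6.10) and the potassium channel gene KCNH1 (-5.53) were next lowest, then PSAT1, an enzyme of serine synthesis (-5.52), and NECTIN3, LRFN5 and NLGN4X (-5.45 to -5.08). The highest in OHTR were CEACAM6 (90.2-fold), the disulfide isomerase family genes AGR2 (68.3-fold) and AGR3 (36.3-fold), the actin-bundling gene LCP1 (47.7-fold) and complement C3 (36.5-fold). CRISP3, SYTL5, the ectonucleotidase gene ENTPD1, the aldehyde oxidase gene AOX1 and the steroid glucuronidation gene UGT2B15 were between 34.0-fold and 26.4-fold higher. In all, 725 genes were at least 2-fold higher in OHTR and 547 lower. The lower side of these folds lies near the low end of the arrays in most cases, so their sizes depend on background there.

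By list under siNeg, estrogen-induced genes had a median of -0.74 (interquartile range -1.58 to -0.07, percentile 0), with 14 of 24 at least 1.5-fold lower in OHTR and 2 higher, TFF1 at -2.63 and PGR at -2.53 among them. ESR1 differed by -0.50. G2/M genes (-0.40) and fatty acid synthesis genes (-0.30) also lay below the central 95%. p53 targets lay above (0.54, percentile 99.9), with TP53INP1 at 2.46 and AEN at 1.44, as did unfolded protein genes (0.40), with the disulfide isomerase gene PDIA4 at 1.89 and DDIT3 (CHOP) at 1.80. G1/S genes (0.26), NF-kB targets (0.06), interferon-stimulated genes (-0.01), hypoxia genes (0.00), luminal genes (0.09), basal genes (0.29), receptors and adaptors (-0.33), cholesterol genes (0.11), AHR and NRF2 targets (0.28), drug transporters (0.25), BCL2 family genes (0.31), immediate early genes (0.45), other TRIM genes (0.08) and reference genes (-0.07) lay inside. ABCC2, a drug efflux pump, was 13.8-fold higher in OHTR within the transporter list, and IGF1R was at -2.76 within the receptor list. Basal genes had a mean of -0.14 beside their median of 0.29. With list means the unfolded protein (percentile 87.2) and fatty acid (7.16) lists lay inside, while luminal genes (mean 0.66, percentile 99.96) and AHR and NRF2 targets (mean 0.73, percentile 99.8) lay above. The fatty acid list also lay inside among unmatched random lists. Without the expression filter the medians of receptors and adaptors, drug transporters and NF-kB targets turned to 0.05, -0.05 and -0.11.

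Under siTRIM47, OHTR and MCF-7 shared 7 of the 10 lowest and 5 of the 10 highest genes with the siNeg comparison, and the G2/M median was lower still, at -1.05 against -0.40. GREB1 (-11.60), PCDH7 (-9.27), PCDH10 (-8.75), CDH12 (-8.25) and KCNH1 (-6.39) were lowest, with the galectin gene LGALS1 (-5.75), OLFM3, NECTIN3, HMCN1 and GRIA2. AOX1 was 83.1-fold higher, UGT2B15 53.6-fold, PSG9 44.1-fold, SYTL5 42.6-fold and CEACAM5 42.3-fold, with UGT2B17, the aldo-keto reductase gene AKR1C2, BCAS1, AGR2 and CEACAM6 from 42.6-fold to 37.5-fold. UGT2B15 and UGT2B17, and the AKR1C genes, are near-identical copies whose probes could share signal. In all, 964 genes were at least 2-fold higher in OHTR and 838 lower. The 27 G2/M genes had a median of -1.05 (interquartile range -1.15 to -0.87, percentile 0), with 25 at least 1.5-fold lower in OHTR, KIF11 at -1.82 and CDC20 at -1.59. G1/S genes had a median of -0.77, with 18 of 29 at least 1.5-fold lower and MCM10 at -2.48, estrogen-induced genes -0.98 with TFF1 at -3.17, and fatty acid synthesis genes -0.70. Interferon-stimulated genes (0.78), p53 targets (0.69), cholesterol genes (0.59), immediate early genes (0.69) and hypoxia genes (0.48) lay above. Drug transporters (median -0.04, mean 0.29), PKC, PKD and NF-kB components (0.02 and -0.13) and reference genes (0.00 and -0.12) lay inside with a mean of the other sign. Without the expression filter the immediate early list lay inside (percentile 80.8), and with the filter at the 75th percentile so did the fatty acid (4.03) and hypoxia (95.01) lists. Luminal genes (mean 0.82, percentile 99.98) and AHR and NRF2 targets (mean 0.84, percentile 99.9) lay above with list means, AHR and NRF2 targets and BCL2 family genes (percentile 99.1) also without the filter; with the filter at the 75th percentile the AHR and NRF2 median turned from 0.30 to -0.27. ESR1 was at 11.36 and 11.37 in OHTR and MCF-7. The OHTR siTRIM47 array also enters the siTRIM47 comparison in OHTR, so the low G1/S and high interferon medians of both comparisons are not independent.

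**Figure D3:**
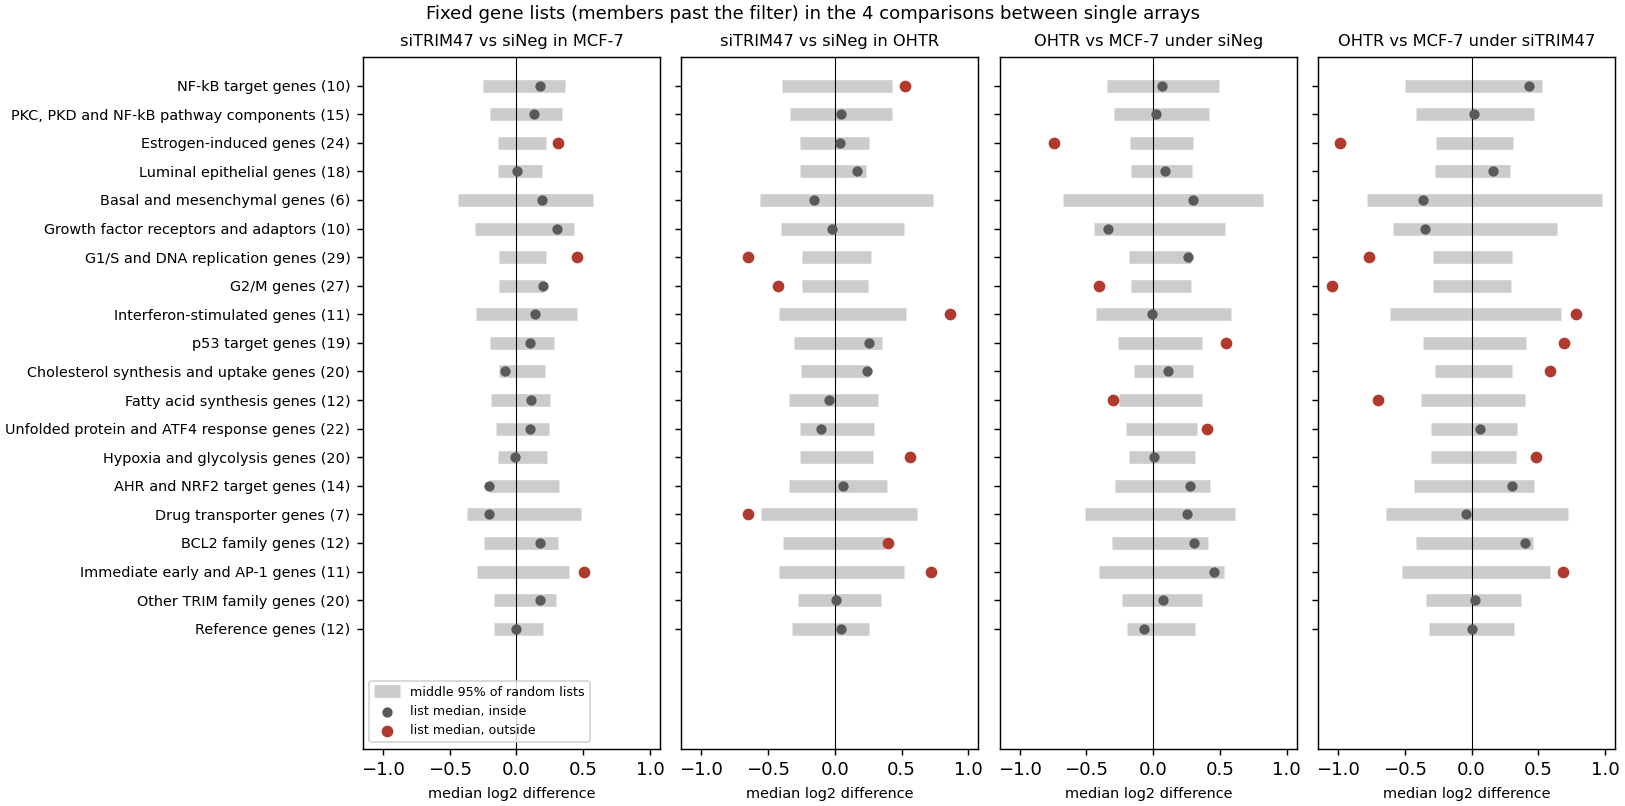
Points give the median log2 difference of each gene list, with the number of members past the filter in brackets, in the 4 comparisons between single arrays, and grey bars span the central 95% of 10000 random lists matched on expression. Red points lie outside the bars, 25 of the 80 medians against 4 expected for lists of genes drawn at random. Members of a list can vary together and the comparisons share arrays, so the excess over 4 does not exclude chance. The G1/S list lies above its bar in MCF-7 and below it in OHTR with siTRIM47.

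Over both siRNAs, 12 of 24 estrogen-induced genes fell in OHTR, and CEACAM6, AGR2 and AOX1 rose most. GREB1 fell by 10.66 on the log2 scale in OHTR relative to MCF-7 (SE 0.37, limma adjusted p = 5.92e-08), PCDH7 fell by 9.23 (SE 0.24) and the trefoil factor gene TFF1 fell by 2.90 (SE 0.25). CEACAM6 rose 58.1-fold (5.86, SE 0.31), AGR2 51.7-fold, AOX1 49.9-fold and the drug efflux pump gene ABCC2 9.50-fold. The growth factor receptor gene IGF1R fell by 3.07 (SE 0.26) and the caveolin genes CAV1 and CAV2 fell 5.65-fold and 6.12-fold. PRKCE, which encodes protein kinase C epsilon, fell 2.79-fold (SE 0.24 on the log2 scale, adjusted p = 0.0017), and the protein kinase D genes PRKD2 and PRKD3 fell by 0.93 and 0.79, while PRKCD rose by 1.01. UGT2B15, SYTL5, LCP1, AKR1C2, AGR3, C3 and ENTPD1 also rose among the 10 highest, and PCDH10, CDH12, KCNH1, GRIA2, NECTIN3, OLFM3, LGALS1 and HMCN1 fell among the 10 lowest.

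In limma's additive fit, 1145 genes rose and 898 fell in OHTR at an adjusted p under 0.05, and 3277 of 9399 had an unadjusted p under 0.05. Of 24 estrogen-induced genes 12 fell and the lysosomal protease gene CTSD rose; adjusted over the list alone, 14 fell and 1 rose. Those that fell included the progesterone receptor gene PGR (-2.09), SGK3 (-1.95), TFF3 (-2.06), MYB (-1.56) and IGFBP4 (-1.47). Of 27 G2/M genes 8 fell, and 18 adjusted over the list alone, but without the expression filter 2 of the 8 kept their call, TOP2A and CENPF. Of 29 G1/S genes POLE2, CHAF1B and RFC4 fell by either adjustment, CHAF1B without a call when the filter was left out. Of 19 p53 targets 7 rose (8 adjusted over the list alone), led by TP53INP1 (2.93), GDF15 (1.94) and AEN (1.56). Of 22 unfolded protein genes 4 rose and 2 fell, with PDIA4 at 1.28 and PSAT1 at -4.70 (list alone: 7 rose, 3 fell; 3 of the 6 kept without the filter). JUN, JUNB and IER2 rose and DUSP5 fell among 11 immediate early genes (list alone: 4 rose, 1 fell). Of 14 AHR and NRF2 targets CYP1A1, CYP1B1, AKR1C1 and AKR1C2 rose (list alone: 5 rose, 3 fell), and of 20 hypoxia genes the glucose transporter and hexokinase genes SLC2A1 and HK2 and ADM rose, 3 by either adjustment.

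Of 10 NF-kB targets TNIP1, IER3 and PLAU rose and NFKBIZ fell in OHTR, the same counts adjusted over the list alone. Of 15 PKC, PKD and NF-kB components 1 rose and 3 fell (list alone: 2 rose, 3 fell). Of 18 luminal genes XBP1, ELF3, AGR2, AGR3 and CLDN4 rose and MUC1 fell, and of 6 basal genes CD44 and TGFBI rose and CAV1 and CAV2 fell, the same counts by either adjustment. Of 10 receptors and adaptors INSR, IRS1 and IGFBP5 rose and IGF1R, FGFR4, MET and TGFA fell, again by either adjustment, but IRS1 and MET lost their call without the expression filter. OAS1 and PARP9 rose among interferon-stimulated genes, MVD and SC5D rose and FDPS fell among cholesterol genes, BAX and HRK rose in the BCL2 family, ABCC2 rose among transporters, TRIM2 and TRIM28 rose and TRIM45 fell among TRIM genes (TRIM2 alone without the filter), and the reference gene TBP fell, with unchanged counts adjusted over the list alone. ACACA, ACACB and FADS2 fell among 12 fatty acid genes (list alone: 4 fell). Limma called 0 of the immune and fibroblast markers over all genes, with 1 of each at an unadjusted p under 0.05, both higher and called when adjusted over the list alone. ESR1 differed by -0.25 (SE 0.25, adjusted p = 0.52). Without the expression filter 1383 of the 2043 called genes remained called, and of 103 named genes 23 lost their call, PRKD3, CDC20 and XBP1 among them. The line effect includes the OHT in the medium of OHTR, which the design does not separate from the line.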

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

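The tests of a trend with intensity and of dim probe sets were chosen before their results were seen, those of a differing response, off-target silencing, loss of TRIM47, ESR1 level and OHT after the result was seen, and that of swapped labels after the data were seen. A list median counted against an explanation when it lay outside random lists and below -0.36 by more than its bootstrap SE over members. The -0.36 is the single-gene yardstick, computed from these same arrays and fixed for this use before the results. The SE was a spread chosen after the values were seen. It treats members that can vary together as independent, and it holds no error between arrays or cultures. What is argued against below is therefore limited to these arrays. Of 2 other bars tried, a whole 95% interval below -0.36 would have left open the intensity trend for the estrogen-induced genes, and an interval below -0.2 would have excluded dim probe sets for the G1/S genes.

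DNA replication genes were lower with siTRIM47 in OHTR (median of the G1/S list -0.65) and higher in MCF-7, and MCM10 led with a difference between the responses of -2.93. A trend with intensity left in the deposited values was argued against by a median of -0.63 after cyclic loess (bootstrap SE 0.10). This is a weak test, since RMA had already quantile normalised the arrays and left cyclic loess little to remove. For noise of dim probe sets, the 20 members past the filter at the 75th percentile had a median of -0.48 (bootstrap SE 0.15). That met the criterion against it fixed before the results, below -0.36 and below random lists (percentile 0.12). It was left open only by the spread added later, since -0.48 is not below -0.36 by more than its SE. A response that differs between the lines may account for the pattern, with a median over members of -1.002 for OHTR minus MCF-7, but with 1 array per condition this and a difference between cultures cannot be told apart.

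The responses of both lines went together across genes, with an r of 0.55 also after cyclic loess. That argued only against an intensity-dependent trend left after RMA's quantile normalisation, which leaves little for such a test to find. Loss of TRIM47 and off-target silencing by the same siRNA could each give a shared response. Off-target silencing might favour lower genes. The ratio of genes 4-fold lower in both lines to genes 4-fold higher in both was 1 (7 and 7, exact 95% interval 0.30 to 3.34). At 2-fold, 154 genes were lower in both lines and 132 higher. These counts do not decide, since the ratio that off-target silencing would give is not known. Loss of TRIM47 could give a larger response in OHTR, where TRIM47 was higher, and the SD of the response over genes was 1.33 times that in MCF-7. A general difference between the lines or array noise could also give this, and the SD does not measure the shared part of the response alone. TRIM47 itself differed by -0.23 in MCF-7 and -1.02 in OHTR. Among the 500 genes of the nearest mean level, 35.6% lay below the MCF-7 value and 0.8% below the OHTR value. Its levels sit near the low end of the arrays, so they measure its loss weakly. These explanations cannot be told apart without a second siRNA or a rescue, which were not analysed here.

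Estrogen-induced genes were lower in OHTR, also under siTRIM47 (median -0.98, bootstrap SE 0.31), where ESR1 RNA differed by -0.01. This argued against a lower ESR1 RNA level as the only cause on that pair of arrays. A part played by ESR1 stayed open, since receptor protein was not measured and OHTR was kept in OHT. An intensity-dependent trend left in the deposited values was argued against by a median of -0.79 under siNeg after cyclic loess (bootstrap SE 0.25, 95% interval -1.30 to -0.30). RMA had already quantile normalised these values, so this test too is weak. The OHT in the medium of OHTR, which occupies the estrogen receptor, may account for the pattern, and so might a stable loss of estrogen response. With 0 arrays of OHTR grown without 4-hydroxytamoxifen used here, these cannot be told apart.

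With the siRNA labels of the OHTR arrays swapped, limma called 0 genes (19 at an unadjusted p under 0.05), which follows from the correlation of the responses and decides nothing more. Of 1429 transcript clusters with no listed gene past the filter, 24 were at least 2-fold apart the same way in both lines, 14 higher and 10 lower with siTRIM47.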

How the results depend on the processing

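No leave-one-out analysis was possible, because leaving out 1 of 4 arrays leaves 0 residual degrees of freedom. The additive fit pairs the arrays by line, and no further pairing of cultures was possible with 1 array per condition. No named additive call and no list median outside random lists changed direction; 32 alternative values of list medians inside them and 3 of named genes did. Of main results, 72 of 101 alternatives kept counts within 1.5 times and correlations within 0.1 on Fisher's z scale. With the filter at the 75th percentile, where fewer genes were counted, genes at least 2-fold higher and lower were 112 and 120 (siTRIM47 in MCF-7), 244 and 292 (siTRIM47 in OHTR), 339 and 209 (OHTR against MCF-7, siNeg) and 476 and 397 (siTRIM47); the additive line effect gave 734 and 538 calls, the difference of responses 285 genes, and the correlation of responses was 0.63. At 1.5-fold, a looser threshold, the same 4 pairs of counts were 1076 and 842, 1615 and 1468, 1697 and 1357, and 1943 and 1863, and the difference of responses 2564. Without the filter 110 genes rose and 118 fell with siTRIM47, 1548 differed between the responses and the correlation was 0.40. With an intensity trend in eBayes 658 rose and 613 fell; the cause was not tested. With the OHTR siRNA labels swapped, an alternative chosen after the data were seen, limma called 0 rising and 0 falling genes (19 at an unadjusted p under 0.05), an outcome the correlation of the responses fixes.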

Other observations

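Targets of AHR and NRF2, which control the metabolism of foreign compounds and the defence against oxidants, were split by siTRIM47 in OHTR, with 4 of 14 at least 1.5-fold higher and 5 lower (median 0.07). The balance depends on dim members, since with the filter at the 75th percentile the 7 members left had a median of -0.55 (percentile 1.07). The heme oxygenase gene HMOX1 was 3.56-fold higher, CYP1A1 3.10-fold and AKR1C1 2.52-fold, while GCLM, a subunit of the enzyme that limits glutathione synthesis, was 2.63-fold lower. In the same cells IGFBP5, which binds insulin-like growth factors, was 4.11-fold higher and FGFR4 2.70-fold lower. Of 20 other TRIM genes in OHTR 4 were at least 1.5-fold higher, led by TRIM41 (2.56-fold) and TRIM2 (2.34-fold), and 1 was lower, with a median of 0.01. Over all genes 17.2% were at least 1.5-fold higher and 15.6% lower in this comparison, so the 4 higher TRIM genes are near that share. Of 22 unfolded protein and ATF4 response genes in OHTR 3 were at least 1.5-fold higher and 5 lower, not far from those shares (median -0.10, inside random lists). DDIT4 and ATF3 were 3.62-fold and 2.24-fold higher, and the serine synthesis gene PHGDH and the cystine transporter gene SLC7A11 2.83-fold and 2.35-fold lower.

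The test of neighbouring genes was chosen before its result was seen, with bounds set for and against regional copy number or regional silencing. The correlation found under siNeg lay between those bounds, so the test decided neither way. Genes next to each other on the chromosomes differed together between OHTR and MCF-7, with a Spearman correlation of 0.146 over 9374 pairs under siNeg (99th percentile of 1000 shuffles 0.0248) and 0.127 under siTRIM47. For the siTRIM47 responses it was smaller, 0.036 in MCF-7 and 0.0582 in OHTR, and also above the highest of 1000 shuffles (0.0329 and 0.0317). Windows of 25 genes with the highest median lay from HNRNPUL1 to ETHE1 (0.97 under siNeg, 1.02 under siTRIM47) and from MICOS13 to STXBP2 (0.96 and 1.19), and the lowest from UBE2Q1 to GON4L (-0.73 and -0.67); the extremes of 100 shuffles under siNeg were 0.72 and -0.68. The first of these windows, of which 8 of 25 genes belong to the CEACAM and PSG families, was also higher with siTRIM47 (0.50 in MCF-7 and 0.66 in OHTR), which a copy number difference between the lines would not give by itself. Copy number changes acquired by OHTR may account for this correlation of 0.146, as might regional silencing or clusters of related genes, and with no DNA measured here these cannot be told apart. A copy number profile of both lines could show whether copy number differs there, but would not separate regional silencing from clusters of related genes.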
